A study of Homo sapiens with 6 samples.

How the data were processed

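Poly(A) RNA of MDA-MB-231 cells was sequenced as paired-end libraries from 3 repeats in DMSO and 3 in disulfiram with copper (0.2 µM), after 24 h, with the cells of 3 wells pooled per repeat. The table held 58825 human Ensembl genes with a count and an FPKM value for each of the 6 libraries. Columns headed Control were taken as the DMSO samples, the only untreated group in the labels. The count columns were deposited as whole numbers per gene, per the file headers, with no scaling. The FPKM columns were deposited as values per kilobase and per scaled fragment number, per the file headers, and for a count of 0 they list at most 0.0001. The authors' notes name Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 without a role or order; the counter, the strand setting and the annotation version are not given in the sources used here. The notes list a mouse build, mm8, but the genes are human: 58552 of the 58825 gene IDs occur in GENCODE 29, of which 58272 lie on the same chromosome with a start within 1 kb and 47593 have the same start and end, so GRCh38 coordinates are used. No step of alignment or counting was repeated.

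Counts and FPKM come from 1 quantification. For 9021 genes with over 500 counts in every library, the log2 ratio of count to FPKM had a median SD over libraries of 0.00053 once each library's median was removed, and for 91.9% the ratio lay within 5% of exon length times 1 constant. Fits to FPKM are therefore no independent check of fits to counts. The plan made before the data were examined used limma on FPKM unless counts were present, and edgeR in that case, so the counts were used. Counts of 0 in every library were found for 29536 genes.

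Genes were kept by edgeR's filterByExpr with default settings (18229 genes, 13421 of them protein-coding), libraries were scaled by TMM, and DSF/Cu was compared with DMSO by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (all gene tests are two-sided). Standard errors are the absolute log2 fold change over the square root of F. Benjamini-Hochberg adjusted p under 0.05 made a call, over all genes tested. At an unadjusted p under 0.05 there were 8151 genes. The common dispersion was 0.0757. TMM factors averaged 1.07 in DMSO and 0.938 in DSF/Cu. Levels are TMM-scaled CPM with the SD over 3 libraries. Where every library of a group had 0 counts, the fold is a lower bound against 3 counts over the whole group. Libraries of a group were compared for duplication by a chi-square over genes per degree of freedom, which was 45.7 to 58.1, so none is a copy of another.

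The 35 gene lists (857 members found in the table) were written before the data were examined: ferroptosis drivers and suppressors, NRF2, HSF1, ATF4, ATF6 and XBP1, p53, NF-kB, interferon and SREBP2 targets, metallothioneins and zinc export, copper handling, lipoylation, proteasome, the p97 segregase, aldehyde dehydrogenases, iron, glutathione, G1/S, G2/M, apoptosis, fatty acids, glycolysis and hypoxia, the respiratory chain (nuclear and mitochondrial), mesenchymal, stemness, autophagy and lysosome, immediate early, ribosomal protein and histone genes, and markers of luminal, basal, immune and of fibroblast, endothelial and adipocyte cells. Each was tested with camera of limma 3.58.1 with a preset correlation of 0.01 and a prior count of 3, with camera with an estimated correlation, and with fry. KEGG and GO terms as paired with genes in the deposited table (10 to 300 members among tested genes with a term) were tested by two-sided Fisher's exact tests, with the tested genes that carry a term as background.

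Genes were named by a rule set before the data were examined: the 12 largest rises and 12 largest falls among called genes with a symbol, a mean FPKM of at least 5 in the higher group and no overlap between groups; up to 4 called members of each list by adjusted p, and any called member of the ferroptosis lists; 23 genes whatever their result; and up to 3 members by adjusted p of up to 6 terms. Exceptions are named as such. Some genes that meet the rule are not reported here.

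The steps were tested on simulated negative binomial counts for 18229 genes, 200 of them changed. With a first choice of dispersion (edgeR's tagwise values), 4 of 77 genes changed 1.5-fold were recovered, 28 of 61 changed 2-fold and 41 of 62 changed 4-fold, with 3 of 17999 unchanged genes called. After these values were seen, the trended dispersion times the quasi-likelihood variance was used in its place, and 14, 33 and 41 were recovered with 5 unchanged genes called. Which dispersion is nearer to that of the real libraries was not tested, so both are given. In both simulations the planted list and the planted term were called, and 0 of 50 unchanged lists and 0 of 50 random terms. The simulated genes were drawn independently of each other. These counts therefore cannot tell how often lists or terms with correlated members are called falsely. In these simulations most changes of 1.5-fold in a single gene were missed. The real data had far more called genes (3365 raised and 3059 lowered), so the adjusted p is less strict there. The share of changes missed in the real data was not tested.

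Alternatives planned before the data were examined were edgeR with DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, each library left out in turn, and limma on FPKM with pseudocounts of 0.1 and 0.01, other FPKM filters (none, 0.1, 5), rescaling to a common sum (TPM), median-ratio factors, quantile normalization, no trend, robust fits and a replicate block, besides camera with an estimated correlation, fry and terms from genes changed at least 2-fold. Added after the data were seen were limma on log2(FPKM + 1) with a mean FPKM of at least 1 beside the counts, total-count scaling, a replicate block in edgeR, and leaving out genes with unstable replicates. Levels of sex-linked marker genes are not reported. Permutation tests used 100000 draws with SciPy 1.17.1, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures matplotlib 3.10.9.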

Results

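RNA was sequenced from MDA-MB-231 cells, an established human triple-negative breast cancer line, after 24 h in vehicle (DMSO) or in disulfiram with copper (DSF/Cu) at 0.2 µM. Disulfiram is an inhibitor of aldehyde dehydrogenases used against alcohol dependence, and its main metabolite binds copper. Each group held 3 repeats, and each repeat pooled the cells of 3 wells. Nothing in the labels says that the repeats came from separately grown cultures, so the p-values measure the spread between these samples, which may be technical. Total counts per library were 70883177, 63271518 and 62165212 in DMSO and 61633168, 61129485 and 55563223 in DSF/Cu. The first principal component of log2 CPM (counts scaled to a common library size by TMM) held 55.4% of the variance and separated the groups. Pearson correlations across genes were 0.9652 to 0.9747 within groups and 0.927 to 0.9345 between them.

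DSF/Cu was compared with DMSO. The comparison asked how expression of all genes, and of genes tied to ferroptosis (iron-dependent death by lipid peroxidation), changed with the treatment. No sample had disulfiram or copper alone, so their effects cannot be told apart here. After DSF/Cu, most tested genes were raised in the lists of HSF1 targets, metallothioneins and zinc export, NRF2 targets, ATF6 and XBP1 targets and proteasome subunits, and most were lowered in those of DNA replication and mitosis. None of these lists passed when camera, a test of a list against all other genes, estimated the correlation between members (adjusted p from 0.0926 to 0.117). *HSPA1B*, an inducible HSP70 chaperone, rose 79.3-fold, from 162 ± 8.76 to 12870 ± 1784 CPM (SD, n = 3 per group). *HMOX1*, the haem oxygenase that frees iron from haem, rose 42.4-fold, from 22.1 ± 1.10 to 936.5 ± 102 CPM. *MT1X*, a metal-binding metallothionein, rose 22.0-fold, and *KIF20A*, a kinesin of cell division, was 2.65-fold lower.

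Of 18229 genes tested with edgeR's quasi-likelihood test, 3365 were raised and 3059 lowered at a Benjamini-Hochberg adjusted p under 0.05. At least 2-fold, 1352 genes rose and 341 fell, against 1067 and 799 under total-count scaling. With FPKM rescaled to a common sum they numbered 328 and 562, but that fit used limma with a pseudocount of 1 on 11573 genes. It thus differs in method and genes as well as in scaling. The groups did not overlap for 9325 genes (51.2%, against 10% by chance for 3 against 3). Among protein-coding genes, 2794 rose and 2833 fell. Long non-coding genes gave 303 rises and 167 falls, and pseudogenes gave 239 and 54. The split depended on scaling. A few genes took more of the counts after DSF/Cu (the 20 most counted genes held 15.2 ± 0.70% against 11 ± 0.252% in DMSO, SD, n = 3), and scaling by total counts in place of TMM moved the median log2 change of all genes from 0.002 to -0.182. Under that scaling 2356 genes were raised and 4856 lowered, so that 32.7% of calls were rises in place of 52.4%. Changes below are relative to the TMM scaling.

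**Figure D1:**
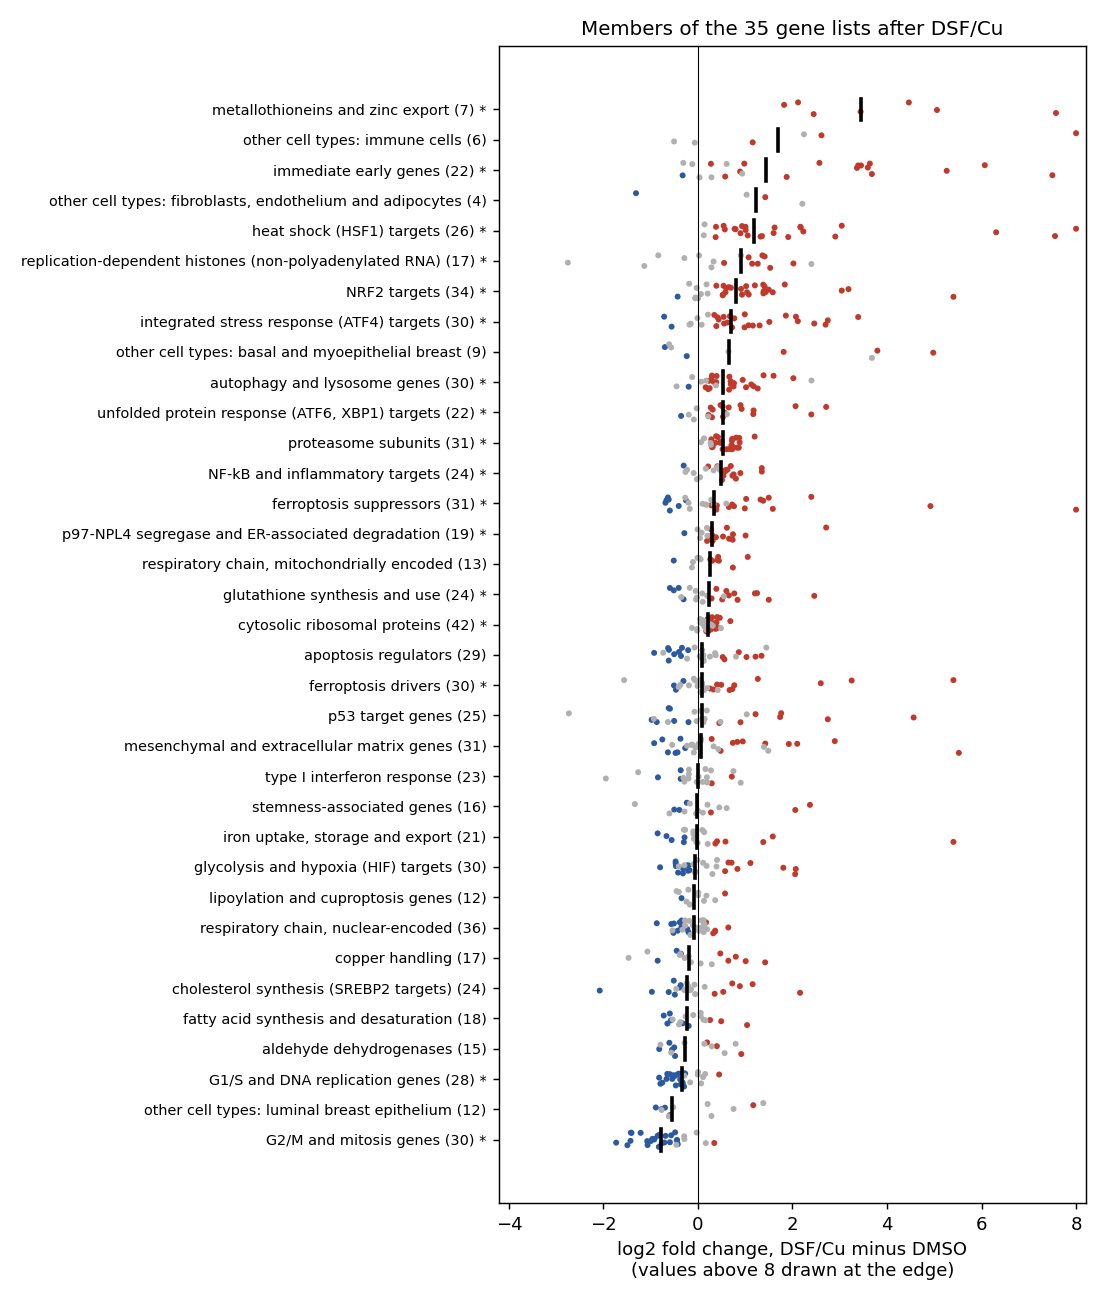
Log2 fold change, DSF/Cu minus DMSO, of each tested member (points, x axis) of the 35 gene lists (ordered by median, with the number of tested members in parentheses). Red points rose, blue points fell and grey points did not pass adjusted p 0.05 in edgeR; black bars mark medians, and an asterisk marks the 17 lists called by camera with a preset correlation. Values above 8 are drawn at the edge. Metallothioneins had the highest median (3.44) and mitotic genes the lowest (-0.79) of the 35.

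Of 26 tested HSF1 targets, 24 rose and none fell (25 and 0 adjusted over the list alone), with a median log2 change of 1.19 (camera adjusted p = 4.23e-16, and adjusted p = 0.117 with an estimated correlation). *DNAJB1*, an HSP40 co-chaperone, rose by 3.04 ± 0.17 (log2, SE), *HSPH1* by 2.17 ± 0.06 and the HSP90 co-chaperone *CHORDC1* by 2.17 ± 0.07. *HSPA6*, another inducible HSP70 gene, went from 0.756 ± 0.262 to 2687 ± 407 CPM. *HSPA6* and its pseudogene *HSPA7* are near-identical in sequence, as are *HSPA1A* and *HSPA1B*, so counts may be split between them. *HSPA1A* rose by 7.55 ± 1.34, and its large error came from the DMSO libraries, which held 5450, 127 and 5626 counts. *CRYAB*, a small heat shock protein gene, had no count in any DMSO library and 56.5 ± 25.8 CPM after DSF/Cu, at least 3945-fold higher against a floor of 3 counts over the group.

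Of 31 proteasome subunits, 27 rose and none fell (28 and 0 adjusted over the list alone, median 0.52, camera adjusted p = 4.98e-13, and adjusted p = 0.117 with an estimated correlation). *PSMC4* was 2.30-fold higher, and *PSMD2* rose by 0.72 ± 0.04 (log2). In the list for the p97 segregase, which pulls ubiquitinated proteins out of complexes, 13 of 19 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 3.83e-05, and adjusted p = 0.0926 with an estimated correlation). *VCP*, which encodes p97, rose by 0.73 ± 0.04, its cofactor *UFD1* by 1.01 ± 0.07 and the other cofactor *NPLOC4* by 0.38 ± 0.07 (not called with FPKM rescaled to a common sum, limma adjusted p = 0.307). Of 30 autophagy and lysosome genes, 23 rose and 1 fell (25 and 1 adjusted over the list alone, camera adjusted p = 3.36e-07, and adjusted p = 0.0926 with an estimated correlation), among them the cargo receptors *SQSTM1* (1.39 ± 0.04) and *TAX1BP1* (1.18 ± 0.05). Of 42 cytosolic ribosomal protein genes, 24 rose and none fell, by little (27 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 4.32e-07, and adjusted p = 0.284 with an estimated correlation). The ribosomal list lost its call after quantile normalization of FPKM (median -0.0518, adjusted p = 0.911) and after rescaling FPKM to a common sum (median -0.0724, adjusted p = 0.377), and over its alternatives the adjusted p ran from 4.08e-08 to 0.911.

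All 7 tested genes of the metallothionein and zinc export list rose (7 adjusted over the list alone, camera adjusted p = 1.41e-07, and adjusted p = 0.117 with an estimated correlation). *MT1E* went from 81.3 ± 3.10 to 882.5 ± 58.2 CPM, *MT2A* from 781 ± 30.6 to 2765 ± 253, and the zinc exporter gene *SLC30A1* from 41.2 ± 0.589 to 224.8 ± 4.32. Metallothionein genes are close copies of each other, so the split between them is uncertain. Of 17 copper handling genes, 5 rose and 3 fell (5 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.922). *MTF1*, the metal-responsive transcription factor, rose by 1.42 ± 0.08, *SOD1* by 1.01 ± 0.08 and the copper importer *SLC31A1* by 0.64 ± 0.06, while the reductase *STEAP3* fell by 0.85 ± 0.08. Among 12 lipoylation genes linked to copper-dependent death, 1 rose, *FDX1* fell by 0.35 ± 0.08 and 10 were not called (1 and 1 adjusted over the list alone, camera adjusted p = 0.631). *FDX1* lost its call without DMSO replicate 2 (adjusted p = 0.0569), DSF/Cu replicate 1 (0.0505) or DSF/Cu replicate 3 (0.052).

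Both ferroptosis lists held genes that moved in each direction. Among 30 tested drivers, 11 rose and 3 fell (11 and 4 adjusted over the list alone), with a median log2 change of 0.09 (camera adjusted p = 0.0363, and adjusted p = 0.119 with an estimated correlation). The rises included *HMOX1*, *SAT1*, the polyamine acetyltransferase (3.25 ± 0.07), the epidermal lipoxygenase *ALOXE3* (2.60 ± 0.32), *CHAC1*, which degrades glutathione (0.77 ± 0.11), *PTGS2* (0.73 ± 0.10) and the ferritinophagy receptor *NCOA4* (0.40 ± 0.08; 0.22 with edgeR adjusted p = 0.0748 under total-count scaling). *ACSL4*, which activates polyunsaturated fatty acids, rose by 0.26 ± 0.07, and *LPCAT3*, which inserts them into phospholipids, fell by 0.51 ± 0.10. The transferrin receptor *TFRC* had a log2 change of -0.09 ± 0.24 and was not called, with 715 ± 262 CPM in DMSO and 673.5 ± 51.8 after DSF/Cu. The drivers' call was lost without DMSO replicate 1 (adjusted p = 0.0507) or DSF/Cu replicate 2 (0.0512). Under total-count scaling the drivers' median was -0.0952 (camera adjusted p = 0.269), where that of all genes was -0.182. Over all alternatives the drivers' median ran from -0.213 to 0.129 and the list's adjusted p from 2.35e-06 to 0.459.

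Among 31 tested ferroptosis suppressors, 15 rose and 7 fell (18 and 7 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.0027, and adjusted p = 0.117 with an estimated correlation). The median was 0.148 under total-count scaling and 0.0274 with FPKM rescaled to a common sum, and over all alternatives it ran from 0.0274 to 0.396 and the adjusted p from 4.8e-10 to 0.117. The rises included the ER chaperone *HSPA5* (2.40 ± 0.06), the ferritin chains *FTL* (1.58 ± 0.07) and *FTH1* (1.38 ± 0.07), the glutamate-cysteine ligase subunits *GCLM* (from 134 ± 8.94 to 379 ± 8.44 CPM) and *GCLC* (0.65 ± 0.10), *TXNRD1* (1.02 ± 0.05) and *NFE2L2*, which encodes NRF2 (0.72 ± 0.04). *SLC7A11*, the cystine importer, rose by 0.39 ± 0.07 and *AIFM2*, the ubiquinone reductase FSP1, by 0.40 ± 0.07 (0.107 with limma adjusted p = 0.233 for FPKM rescaled to a common sum). Lists share members: *FTL*, *FTH1*, *GCLM*, *GCLC*, *TXNRD1* and *SLC7A11* are also on the NRF2 list, as is the driver *HMOX1*. *HSPA5* is also on the ATF6 and XBP1 list, the raised suppressors *CRYAB* and *HSPB1* on the HSF1 list, and *SLC3A2* and *SLC7A11* on the ATF4 list. The rises among suppressors are thus not separate from those of these lists. The desaturase *SCD* fell by 0.60 ± 0.05, *DHCR7* by 0.62 ± 0.09 and the iron exporter *SLC40A1* by 0.67 ± 0.15. The placing of *DHCR7* among the suppressors, and of *PTGS2* among the drivers, is open to question and was not tested. *GPX4*, the glutathione peroxidase that reduces lipid peroxides, held 96.4 ± 7.62 CPM in DMSO and 85.5 ± 11.7 after DSF/Cu, a log2 change of -0.17 ± 0.11 that was not called (edgeR adjusted p = 0.285). These small changes depended on scaling: under total counts *GPX4* was called lower (-0.362, adjusted p = 0.0328), and *SLC7A11* (0.205, adjusted p = 0.0845) and *ACSL4* (0.0712, adjusted p = 0.524) were not called. *ACSL4* lay at -0.0371 with FPKM rescaled to a common sum, and was not called without DMSO replicates 1, 2 or 3 or DSF/Cu replicates 2 or 3 (adjusted p from 0.0589 to 0.0968). *SLC40A1* was not called without DMSO replicate 2 (adjusted p = 0.0551) or DSF/Cu replicate 3 (0.0552).

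**Figure D2:**
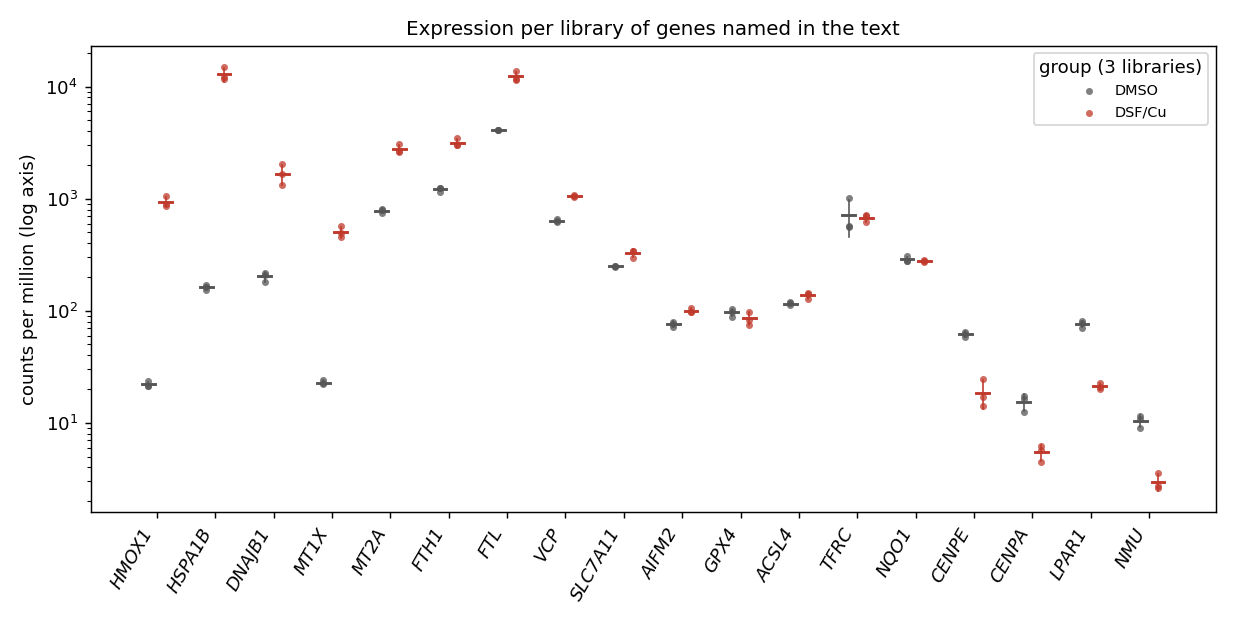
TMM-scaled CPM (y axis, log scale) of 18 genes (x axis) in each of the 3 DMSO libraries (grey) and the 3 DSF/Cu libraries (red); horizontal bars are means and vertical bars 1 SD. *HMOX1* went from 22.1 to 936.5 and *FTL* from 4111 to 12320 on average, while the libraries of *GPX4*, *TFRC* and *NQO1* overlapped between groups.

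Of 34 NRF2 targets, 25 rose and 1 fell (27 and 2 adjusted over the list alone, median 0.80, camera adjusted p = 4.75e-11, and adjusted p = 0.0926 with an estimated correlation). The aldo-keto reductase *AKR1C1* rose by 3.04 ± 0.12 and the sulfiredoxin gene *SRXN1* by 1.38 ± 0.05. *AKR1C1* is a close copy of *AKR1C2*, so its count is uncertain. *NQO1*, a commonly used NRF2 target, had a log2 change of -0.05 ± 0.05 (edgeR adjusted p = 0.521; -0.236 with adjusted p = 0.015 under total-count scaling). Of 24 glutathione genes, 11 rose and 4 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.0272, and adjusted p = 0.117 with an estimated correlation). *CTH*, which makes cysteine, rose by 2.46 ± 0.09, and glutathione reductase, *GSR*, was 2.30-fold higher. The glutathione list was not called without DSF/Cu replicate 1 (camera adjusted p = 0.0811), under total-count scaling (0.0601), with the replicate block in edgeR (0.0529), with no FPKM filter (0.0944) or with a mean FPKM of at least 0.1 (0.0511). Its median was -0.00329 with FPKM rescaled to a common sum, and over its alternatives the adjusted p ran from 1.31e-06 to 0.117. Among 21 iron genes, 6 rose and 5 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.798), the rises led by *HMOX1* and the ferritin chains. With DESeq2 the iron list was called raised (cameraPR adjusted p = 0.00439, median -0.0277), and over its alternatives the adjusted p ran from 0.00124 to 0.997.

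Of 30 ATF4 targets, 23 rose and 2 fell (24 and 4 adjusted over the list alone, camera adjusted p = 7.14e-09, and adjusted p = 0.0926 with an estimated correlation), with *SESN2* at 2.75 ± 0.10 and *PPP1R15A*, which reverses eIF2α phosphorylation, at 2.70 ± 0.10. Of 22 ATF6 and XBP1 targets, 16 rose and 1 fell (17 and 2 adjusted over the list alone, camera adjusted p = 1.73e-06, and adjusted p = 0.117 with an estimated correlation), with *HERPUD1* at 2.71 ± 0.09 and *DNAJB9* at 2.06 ± 0.09. Of 22 immediate early genes, 15 rose and 1 fell (15 and 2 adjusted over the list alone, camera adjusted p = 1.41e-07, and adjusted p = 0.117 with an estimated correlation). *FOS* went from 2.19 ± 0.584 to 147 ± 18.1 CPM, and *DUSP1* and *JUNB* rose by 3.59 ± 0.09 and 3.64 ± 0.11. Of 24 NF-kB and inflammatory targets, 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 1.11e-04, and adjusted p = 0.117 with an estimated correlation), and *CXCL8* went from 1082 ± 61.8 to 2760 ± 12.5 CPM.

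Of 30 G2/M and mitosis genes, 24 fell and 1, *CKS2*, rose (25 and 1 adjusted over the list alone, median -0.79, camera adjusted p = 1.04e-11, and adjusted p = 0.117 with an estimated correlation). *CENPE*, a kinetochore motor, fell by 1.73 ± 0.20, *KIF20A* by 1.41 ± 0.08 and *CCNB1*, cyclin B1, by 1.21 ± 0.06. Of 28 G1/S and DNA replication genes, 19 fell and 1, *CCNE2*, rose (19 and 1 adjusted over the list alone, median -0.34, camera adjusted p = 7.24e-06, and adjusted p = 0.117 with an estimated correlation). *CKS2* and *CCNE2* were named after their values were seen. *UHRF1* fell by 0.82 ± 0.06 and the replicative helicase subunits *MCM5* and *MCM6* by 0.76 ± 0.06 and 0.65 ± 0.06. Replication-dependent histone genes did not follow: 8 of 17 rose and none fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.0181, and adjusted p = 0.117 with an estimated correlation). Most histone mRNAs lack a poly(A) tail, so a poly(A) library measures them in part only.

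The aldehyde dehydrogenases, the enzyme family that disulfiram inhibits, changed in both directions. Of 15 tested genes 3 rose and 5 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.476). *ALDH2* rose by 0.92 ± 0.08, and *ALDH1B1* fell by 0.82 ± 0.08. *ALDH1A1* was below the count filter, with 0 counts in each DMSO library and 4, 12 and 0 after DSF/Cu. Among 31 mesenchymal and matrix genes 10 rose and 7 fell (10 and 7 adjusted over the list alone, camera adjusted p = 0.415). With DESeq2 this list was called raised (cameraPR adjusted p = 4.12e-05), and over its alternatives the adjusted p ran from 4.12e-05 to 0.989. *CCN2* rose by 2.10 ± 0.06 and *SNAI1* by 5.52 ± 0.23, while *VIM*, the intermediate filament of mesenchymal cells, fell by 0.27 ± 0.07 and lost its call without DMSO replicate 2 (adjusted p = 0.0573), DSF/Cu replicate 2 (0.0633) or DSF/Cu replicate 3 (0.0592).

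Lists of metabolism, death and lineage held changes in both directions, and with TMM scaling of all 6 libraries in edgeR camera called none of them. p53 targets gave 7 rises and 6 falls of 25 (7 and 7 adjusted over the list alone, camera adjusted p = 0.697), with *GADD45A* up by 1.74 ± 0.09 and the exonuclease gene *AEN* down (-0.59 ± 0.06). Apoptosis regulators gave 6 and 9 of 29 (7 and 9 adjusted over the list alone, camera adjusted p = 0.798), with *BNIP3L* up by 1.34 ± 0.07 and *BOK* down (-0.93 ± 0.08). Cholesterol synthesis genes gave 6 and 8 of 24 (6 and 8 adjusted over the list alone, camera adjusted p = 0.337): *IDI1* rose by 0.89 ± 0.06, and *ACAT2* fell by 0.39 ± 0.05. Fatty acid synthesis genes gave 3 and 6 of 18 (3 and 7 adjusted over the list alone, camera adjusted p = 0.276), with *FASN* down (-0.65 ± 0.08). This list was called lowered with no FPKM filter (adjusted p = 0.00501, and from 0.00501 to 0.612 over its alternatives). Glycolysis and hypoxia genes gave 8 and 11 of 30 (8 and 11 adjusted over the list alone, camera adjusted p = 0.986), with *ADM* up by 2.07 ± 0.08 and *SLC2A3* by 2.06 ± 0.12. Nuclear-encoded respiratory chain genes gave 5 and 11 of 36 (6 and 12 adjusted over the list alone, camera adjusted p = 0.289), with *CYC1* down (-0.87 ± 0.09), and the 13 mitochondrially encoded ones 7 and 1 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0655). The nuclear-encoded list was called lowered under total-count scaling (camera adjusted p = 0.00671), with no FPKM filter (9.53e-05), with a mean FPKM of at least 0.1 (0.0073) and with FPKM rescaled to a common sum (0.0156), and its adjusted p ran from 9.53e-05 to 0.688 over its alternatives. The mitochondrially encoded list was called raised without DMSO replicate 3 (adjusted p = 0.0325), without DSF/Cu replicate 2 (0.0232) or with DESeq2 (0.0334), and lowered after quantile normalization of FPKM (median -0.0629, adjusted p = 0.0309). Its adjusted p ran from 0.0232 to 0.688 over its alternatives. Type I interferon genes gave 2 and 3 of 23 (2 and 3 adjusted over the list alone, camera adjusted p = 0.798), and stemness-associated genes 3 and 3 of 16 (3 and 3 adjusted over the list alone, camera adjusted p = 0.986).

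Markers of other cell types were tested as lists too, and camera called none. Luminal genes gave 1 rise and 4 falls of 12 (1 and 4 adjusted over the list alone, camera adjusted p = 0.261), with the keratins *KRT8* (-0.89 ± 0.10), *KRT18* (-0.60 ± 0.07) and *KRT19* (-0.77 ± 0.05) lower and *XBP1*, also an unfolded protein response gene, higher by 1.17 ± 0.17. Basal genes gave 3 rises and 2 falls of 9 (4 and 2 adjusted over the list alone, camera adjusted p = 0.476). *KRT17* went from 0.182 to 5.79 CPM and *TP63* from 0.238 to 3.33. Immune genes gave 3 rises of 6 and no fall (3 and 0 adjusted over the list alone, camera adjusted p = 0.194), among them *CSF1R* (1.83 to 4.08 CPM). The fitted log2 changes of the other rises were larger: with each library left out in turn, *CD14* rose by 2.27 to 3.21 and *ITGAM* by 8.17 to 9.46. On log2(FPKM + 1) with no FPKM filter, *ITGAM* rose by only 0.195 and was not called (limma adjusted p = 0.14), so the size of its rise is uncertain. Of the 6 tested immune genes, 1 had 0 counts in every library of a group, where only a lower bound of the fold can be given. Fibroblast, endothelial and adipocyte genes gave 1 and 1 of 4 (1 and 1 adjusted over the list alone, camera adjusted p = 0.6). The median and the mean of the tested members had opposite signs for iron genes (-0.03 and 0.32), glycolysis genes (-0.06 and 0.21) and stemness genes (-0.02 and 0.16), and fry's direction was up for these and for copper handling genes, whose median was -0.20.

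By size of change, the largest rises among genes with a mean FPKM of at least 5 in the higher group included several that were nearly silent in DMSO. *ARC* went from 0.606 ± 0.191 to 347 ± 73.2 CPM, *GADD45G* from 0.103 ± 0.13 to 61.3 ± 15.1 and *MMP10* from 0.0722 ± 0.0838 to 16.6 ± 2.94. The long non-coding genes *LINC02158* and *LINC01647* reached 15.4 ± 3.75 and 8.51 ± 1.76. *TEX19* and the pseudogene *CEACAMP10* had no DMSO counts and were at least 1291-fold and 1235-fold higher. *RPL17-C18orf32*, also without DMSO counts, is a read-through gene that shares exons with *RPL17* and *C18orf32*, so its value is uncertain. The largest falls were *LPAR1*, a lysophosphatidic acid receptor (1.85 ± 0.09 lower on the log2 scale), *SHISA3*, *NMU*, *FERMT1*, *CTXN1*, *CENPE*, *SAPCD2*, *VPS9D1-AS1*, *METAP1D*, *PSRC1*, *CENPA* and *ADGRE5*, between 3.62-fold and 2.76-fold lower.

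Terms paired with genes in the deposited table were tested too. Fisher's exact tests treat genes as independent, and the p-values of terms do not measure the spread between libraries. The list tests estimated a correlation of 0.229 between proteasome subunits, 0.0925 between replication genes and 0.156 between mitotic genes. With the correlation estimated, camera called none of these lists (adjusted p = 0.117 each). Lists with an estimate under the preset 0.01 lost their call in that setting too, so the losses cannot be put down to correlation alone. By Fisher's exact tests with Benjamini-Hochberg adjustment, 10 of 303 KEGG terms were enriched among raised genes and 8 among lowered genes. Proteasome led the first, with 31 of 42 members raised against 10.1 by the overall rate (adjusted p = 3.22e-09), followed by protein processing in the endoplasmic reticulum with 66 of 153 against 36.6 (adjusted p = 1.86e-05). DNA replication led the second, with 23 of 36 lowered against 7.87 (adjusted p = 1.93e-05), followed by cell cycle with 49 of 119 against 26.0 (adjusted p = 2.41e-04). Of 3257 GO terms, 131 were enriched among raised and 42 among lowered genes, among the latter protein glycosylation (54 of 143 against 30.2, adjusted p = 0.00139), with log2 changes of -0.83 for *POFUT1* and -1.01 for *GALNT6*, though the member *GOLGA2* rose by 0.70. Leaving out a library moved some counts by over 1.5 times. The KEGG terms among raised genes numbered 18 without DSF/Cu replicate 3. Those among lowered genes numbered 3 without DMSO replicate 2, 14 without DMSO replicate 3, 4 without DSF/Cu replicate 1 and 3 without DSF/Cu replicate 3. GO terms among lowered genes numbered 27 without DMSO replicate 1 and 26 without DSF/Cu replicate 1. Among genes raised at least 2-fold, 8 KEGG and 69 GO terms were enriched, led by rheumatoid arthritis (18 of 59 against 4.73, adjusted p = 1.18e-04) and by extracellular matrix (38 of 151 against 10.4, adjusted p = 4.95e-09). No KEGG or GO term passed the adjusted p among genes lowered at least 2-fold (8 KEGG and 100 GO terms at an unadjusted p under 0.05).

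*HMOX1* lies on chromosome 22 from 35380361 to 35390293, *HSPA1B* on chromosome 6 from 31827738 to 31830254, *FTH1* on chromosome 11 from 61959718 to 61967634 and *GPX4* on chromosome 19 from 1103926 to 1106790, in the coordinates of the deposited table, which match GRCh38. All 17 lists called by camera with a preset correlation lost their call with an estimated correlation, when limma's camera called none of the 35 (14 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 32. The estimate was under the preset 0.01 for the autophagy (-0.0133), p97 (-0.00812), driver (-0.0217), glutathione (-0.031) and histone (-0.00443) lists. A higher correlation between members is thus not why these lists lost their call. The unadjusted camera p of the autophagy list went from 7.68e-08 to 0.00364 though its estimate was lower than the preset value. In the other lists that lost their call, the estimate was 0.0166 to 0.279. How much of their loss came from correlation was not tested. In the heat shock, metallothionein, proteasome, ribosomal and histone lists, where edgeR called 0 members lowered, 0 were lowered at an unadjusted p under 0.05 as well and 0 were called lowered by DESeq2. With *CRYAB* and *MT1M* set at their lower bounds, the medians of the suppressor, heat shock and metallothionein lists stayed at 0.331, 1.19 and 3.44. A median does not move when a value above it is lowered but stays above it. This therefore says nothing of the list tests, which were not repeated at the bounds.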

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

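Total-count scaling, limma on log2(FPKM + 1), the replicate block in edgeR and leaving out unstable genes were chosen after the data were seen; the other alternatives were planned. The counts of raised, lowered, 2-fold raised and 2-fold lowered genes were 3365, 3059, 1352 and 341. Under total-count scaling 4856 genes were lowered and 799 at least 2-fold; this scaling divides by totals of which a few raised genes hold more after DSF/Cu. Raised genes numbered 1802 with limma on log2(FPKM + 1), 1803 and 1797 with pseudocounts 0.1 and 0.01, 2235 with no FPKM filter, 1193 with a mean FPKM of at least 5 (fewer genes tested), 1330 as TPM, 1790 without trend, 1788 with robust fits and 1661 with the limma block. Lowered genes numbered 4635 with a mean FPKM of at least 0.1 and 5351 as TPM. Genes raised at least 2-fold numbered 310 with limma on log2(FPKM + 1), 438 and 457 with pseudocounts 0.1 and 0.01, 341 with no FPKM filter, 351 and 192 with a mean FPKM of at least 0.1 and 5, 328 as TPM, 440 with median-ratio factors, 370 after quantile normalization, 309 without trend, 306 with robust fits and 305 with the block. Genes lowered at least 2-fold numbered, in those settings without the pseudocounts, 144, 135, 142, 109, 562, 48, 73, 143, 141 and 141; a pseudocount of 1 shrinks folds of genes at low FPKM, and otherwise the cause was not tested. Without each library in turn the 4 counts ran from 2786 to 2953, 2284 to 2550, 1173 to 1292 and 290 to 412. Genes called in opposite directions numbered 8 as TPM and 6 after quantile normalization, and 0 in the other settings. The drivers' median (0.0904) lost its call at 0.0725 with no filter on low counts, -0.0952 under total counts, -0.0913 with limma on log2(FPKM + 1), -0.0952 and -0.0955 with pseudocounts 0.1 and 0.01, -0.0341 with no FPKM filter, -0.0629 and -0.0775 with at least 0.1 and 5, -0.213 as TPM, 0.0333 after quantile normalization, -0.0913 without trend, with robust fits and with the block, and at 0.0904 with an estimated correlation; without each library in turn it ran from 0.0647 to 0.129. So its sign, too, depends on scaling, which moves all genes. The median of all genes was -0.182 under total counts, -0.167 with limma on log2(FPKM + 1) and -0.304 as TPM, and the drivers' median stayed above it there. It lay below that of all genes with no filter on low counts (0.0725 against 0.085), no FPKM filter (-0.0341 against -0.00752) and DESeq2 (0.0951 against 0.108). The suppressors' median (0.331) lost its call with an estimated correlation (0.331, adjusted p = 0.117), its median ran from 0.0274 to 0.396 over all alternatives, and without each library in turn from 0.297 to 0.396. KEGG terms among raised genes (10) numbered 18 with no filter on low counts, 16 with DESeq2, 6 with a mean FPKM of at least 5, and 7 to 18 without each library; among lowered genes (8) they numbered 14, 15 and 4 in these settings, 3 with the edgeR block, 22 with no FPKM filter, 5 with median-ratio factors, 3 after quantile normalization, 5 with the limma block, 0 from genes changed at least 2-fold, and 3 to 14 without each library. GO terms among raised genes (131) numbered 74 with a mean FPKM of at least 5, 69 from genes changed at least 2-fold and 122 to 168 without each library; among lowered genes (42) they numbered 66 with DESeq2, 22 with limma on log2(FPKM + 1), 21 and 20 with pseudocounts 0.1 and 0.01, 81 with no FPKM filter, 24 with at least 5, 18 as TPM, 25 with median-ratio factors, 17 after quantile normalization, 20 without trend, 21 with robust fits, 23 with the block, 0 from genes changed at least 2-fold and 26 to 44 without each library. Reversed as TPM were *ACSL4* (-0.0371) and *SRC* (-0.00853). Both stayed above the median of all genes in that setting (-0.304), so their signs moved with a shift of all genes. After quantile normalization *MT-ND3* (-0.0502), *MT-ATP6* (-0.0347), the mitochondrially encoded list (-0.0629, camera adjusted p = 0.0309) and the ribosomal list (-0.0518) reversed, the cause not tested. By fry's direction against a negative median, copper handling (-0.196), glycolysis and hypoxia (-0.0594) and stemness (-0.0197) reversed. Of 181 named genes, 155 kept direction and call in every setting in which they were tested and 26 changed in some. DESeq2's lists were tested with cameraPR on its z values, a different method. Some FPKM settings left no gene of the fibroblast, endothelial and adipocyte list. Replicate numbers do not pair the samples: deviations of same-numbered libraries from their group means correlated over genes at 0.021, -0.008 and 0.044, and with the numbers as a block edgeR called 2692 genes raised and 2451 lowered. With 3 libraries per group, small changes such as that of *GPX4* are not settled: it was called lower under total counts (-0.362) and in most FPKM fits.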

Other observations

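The tests of sequencing depth and of heavy-strand position were chosen after the result was seen; the other tests were written before their value was computed, on patterns found in the same data, with bounds set by judgement.

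Among 10451 genes with a middle count of at least 500 in a group, 333 (3.19%) had replicates that differed over 3-fold within a group, thresholds chosen after the data were seen. *MYC* held 548, 10139 and 9905 counts in the DMSO libraries, *CLDN4* 4692, 3886 and 23 after DSF/Cu, and *DAG1* 20107, 1062 and 16454 in DMSO. Adding the counts of overlapping genes brought 14% of the 399 cases under 1.5-fold, which argues against reads shared with them as the main cause, and the library with the most outlying values held 19.8% of them, which argues against 1 poor library. Only 14 of the 333 genes passed the adjusted p, so the calls rest little on them, but a lack of change in such a gene cannot be read from these data. An error in assigning reads to genes, or differences between the cultures, may remain as explanations, and neither was tested.

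Of the tested genes, 210 had 0 counts in every DMSO library, against 11 with 0 in every DSF/Cu library, and 119 of the 210 are protein-coding. *RAI2* reached 7.24 ± 1.42 and *CHGA* 5.48 ± 2.06 CPM after DSF/Cu, at least 505-fold and 383-fold higher against 3 counts over the group (both chosen after their values were seen). Deeper sequencing is argued against by the ratio of mean total counts (0.908, DSF/Cu over DMSO), and reads running on from an active gene within 10 kb upstream by their share: 11% of the 210 against 13.8% of 4791 uncalled genes of like level, a ratio of 0.794 (Fisher's exact test, two-sided, p = 0.26). CPM summed over 382 olfactory receptor genes were 1.41 times higher after DSF/Cu, on at most 191 counts per library, so an even background such as genomic DNA stays open for the lowest of these genes. Induction by the treatment may explain the rest, a hypothesis from the same data.

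Mitochondrial mRNAs of the heavy strand, which are cut from a shared precursor, changed unequally: *MT-ND1* rose by 1.05 ± 0.09 and *MT-ND2* by 0.74 ± 0.07, *MT-CO3* had a log2 change of -0.13 ± 0.05 that was not called, and *MT-ND6*, from the light strand, fell by 0.51 ± 0.09 (genes chosen after their values were seen). Adding the counts of nuclear copies left 100% of the range of log2 changes (1.18 against 1.18). The range runs from *MT-CO3* to *MT-ND1*, with 6260 and 4232 CPM in DMSO. Their copies held 14.9 and 34.5 CPM on average, too few for the sum to change the range. Reads counted on the copies thus do not make the range. Reads left uncounted because they match both would be in neither count, so sharing of reads stays open. Position along the strand gave a rank correlation of -0.385 over 12 genes, which are not independent (permutation test, two-sided, p = 0.22), so a larger rise near the promoters may or may not hold. The bound first set for that test took such a p as evidence against position, which 12 genes are too few to give. Differences in stability between these mRNAs were not tested.

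The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 3365 raised genes, with at most 1 in a direction in any other split, 3059 lowered (highest other 1), 1352 raised at least 2-fold (highest other 1) and 341 lowered at least 2-fold (highest other 1). Gene lists called by camera numbered 17 in the real split and up to 13 in another, so camera with a preset correlation called lists in splits that mix the groups. Every other split holds more DMSO libraries in 1 of its groups, so part of the treatment effect stays in its contrast. Lists called there need not be false calls. The mixing also widens the spread within groups, which makes gene calls unlikely there, so these counts cannot tell how many calls arise by chance.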
